A study of Homo sapiens with 8 samples.

How the data were processed

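Messenger RNA of cultured human portal fibroblasts (PF) and hepatic stellate cells (HSC) was sequenced in 8 libraries, 4 per cell type, from stranded poly(A) libraries on an Illumina NovaSeq. Per the submitters' processing notes, reads were aligned to GRCh38 (hg38) and edgeR was used, without a stated version. The deposited table holds 1 signal value per gene symbol and library for 14450 genes, and its unit is a scaled read count. The values of each library are whole multiples of 1 step (100% within 0.001 reads), so whole reads were recovered by dividing by that step. Totals of these reads were 13809193 to 19092985 per library over the listed genes, and the scaled totals were 935149 to 1114830, so the values are not exact CPM values. A value of 1 rests on 12.4 to 17.1 reads. All 8 columns were used.

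The columns are named by cell type and a number from 1 to 4, and do not show which library came from which donor. A comparison of donor means, contrasts between donors and a cell type by donor term were planned and could not be made. Instead the 8 libraries were compared by cell type, and p-values from this are too small because the 4 libraries of a cell type come from 2 donors. The labels do not say whether PF and HSC donors were the same people. Pairs of closest libraries were found from Pearson correlations over genes, which are not independent replicates, and were used only in alternatives chosen after seeing the data. The pairs may be the 2 libraries of each donor, and pair means would then be the planned donor means, but no label shows this.

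Symbols were matched to GENCODE release 29 on GRCh38 and to tables of older symbols. The 341 names found in none of these tables and 11 names in the class of sex-linked genes fixed for exclusion were left out. A name that stands for more than 1 GENCODE gene, such as RGS5, or is found only as an older symbol was kept, and no position is given for it. Genes with a value of at least 1 in at least 2 libraries were tested, 13145 in all. Values were transformed as log2(value + 1) and fitted with limma 3.58.1 (lmFit, eBayes with trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 differences are PF minus HSC with the standard error of the fit, and levels are means ± SD over 4 libraries. These standard errors are too small for the same reason as the p-values. For KRT7 the standard error was 0.31 with 8 libraries and 0.44 with pair means. The SDs describe the spread over libraries, not over donors.

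The gene lists, 34 in number, were fixed before the data were examined, as were the test, the filter and the rule for named genes, while the use of libraries in place of donor means was settled afterwards. Lists with at least 5 tested genes were tested with camera with a preset correlation of 0.01 and, as an alternative, an estimated correlation. By the rule, named genes were the 10 with the largest difference in each direction that passed the test, with all libraries of 1 cell type above the other and a mean of at least 5 in the higher type, 20 genes named whatever their result, and up to 3 members per list and direction past the test. Clone and locus names, HLA genes, immune receptor segments and genes commonly lost through germline variants were left out of the first part. The rule gave 142 tested genes, from which the text gives all of the first and second parts and examples of the third. Another 13 genes were named after their values were seen, in the plot of genes that differed among libraries of a cell type and among the additional observations.

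Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter or a minimum of 5, quantile normalization, eBayes without trend or robust, an absolute log2 difference of at least 1, and leaving out each library. Alternatives chosen after seeing the data were pair means, pairs as correlated libraries (duplicateCorrelation), edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads and on reads summed over pairs, scaling by total reads, keeping names found in no table and leaving out each pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

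The fits were tested on simulated data in which 200 genes were changed. Without pair structure, limma on 8 libraries recovered 100% of changes of 1 on the log2 scale and called 12 of 12587 unchanged genes. With pairs as unlike as those seen, it recovered 78% and called 999 of 12664 unchanged genes (7.89%). With pairs as correlated, these were 45% and 240 genes (1.90%), and with pair means 0% and 0 genes. The 240 false calls outnumber the 200 changed genes, so most calls with pairs as correlated were false in this simulation. That share depends on how many genes are changed. Camera called none of 99 lists of unchanged genes in either simulation. Simulated genes varied independently of each other, whereas the estimated correlation between real list members reached 0.798 in the proliferation list. The simulation therefore does not show how often camera calls unchanged lists in these data.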

Results

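Bulk RNA sequencing was used to compare 2 mesenchymal cell types of the human liver in culture. Portal fibroblasts (PF) are the fibroblasts that surround the bile ducts and vessels of the portal tract, and hepatic stellate cells (HSC) are the vitamin A-storing pericytes of the sinusoids. Each cell type was represented by 4 libraries, labelled as 2 donors with 2 libraries each. All cells were grown in the same serum-containing medium before lysis. Between 13809193 and 19092985 reads per library fell in the 14450 listed genes. The values are read counts scaled per library, on which a value of 1 stands for 12.4 to 17.1 reads. Libraries are named HSC1 to HSC4 and PF1 to PF4, and these names do not show the donor. Across tested genes, each library had a close partner of its own cell type, namely HSC1 with HSC3, HSC2 with HSC4, PF1 with PF3 and PF2 with PF4. Pearson's r across genes was 0.996 within each of these pairs and at most 0.945 with other libraries of the type. The median chi-square over genes was 1.57 to 1.78 times the value that counting noise gives within these pairs, and 19.6 to 27.6 times between other libraries of a type. Libraries were counted singly because the columns show no donor.

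The comparison of PF with HSC libraries asks which genes set these cell types apart, in a series concerned with effects of PF on hepatocyte functions. PF libraries held more transcripts of PI16, which encodes a peptidase inhibitor of perivascular fibroblasts, at 659.5 ± 84.0 scaled counts (mean ± SD, n = 4) against 2.77 ± 1.30 in HSC. FBLN2, an elastic fibre-associated fibulin, reached 1838 ± 372 against 60.4 ± 40.7, and the keratin KRT7 reached 420.0 ± 120.4 against 9.61 ± 4.06. HSC libraries held more of the intermediate filament gene NES, at 109 ± 82.0 against 2.21 ± 1.66, and of VIPR1, the receptor for vasoactive intestinal peptide, at 191 ± 159 against 6.89 ± 5.89. Of 13145 genes tested with limma on log2(value + 1), 3428 had a Benjamini-Hochberg adjusted p below 0.05, of which 1813 were higher in PF and 1615 higher in HSC. Among these, 674 were higher in PF and 483 higher in HSC by at least 1 on the log2 scale. All 4 libraries of 1 cell type lay above all 4 of the other for 33.6% of tested genes, where chance gives 2.86% for 8 independent libraries but 33.3% for 4 pairs whose partners never part.

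These p-values, and the standard errors given below, are too small, because the 4 libraries of a cell type came from 2 donors. With the libraries of a pair treated as correlated (consensus correlation 0.913), limma called 628 genes, 402 higher in PF and 226 higher in HSC, all of them among the 3428. With each pair averaged to 1 value, limma called 0 genes, with 1607 at an unadjusted p below 0.05 and a lowest adjusted p of 0.0622. If the pairs are the 2 libraries of each donor, which the columns do not show, this fit is the planned comparison of donor means. On reads summed over pairs, edgeR called 0 genes and DESeq2 684. The limma fits on pairs have the same log2 differences as the fit on 8 libraries, so no direction could change there. In edgeR and DESeq2 on summed reads, which use the same reads, all 3428 called genes kept their direction. Scaling by total reads in place of the deposited factors moved the median gene by -0.11 on the log2 scale, and the share of calls higher in PF from 52.9% to 38.2%. Below, a gene said to hold in both tests passed with the libraries as separate and with pairs as correlated. Genes that passed the second test all passed the first, so the first adds no separate support. In simulated data with pairs as unlike as those seen, the second test still called 240 of 12664 unchanged genes. As only 200 genes were changed there, most of its calls were false, so holding in both tests is weak support for a single gene.

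**Figure D1:**
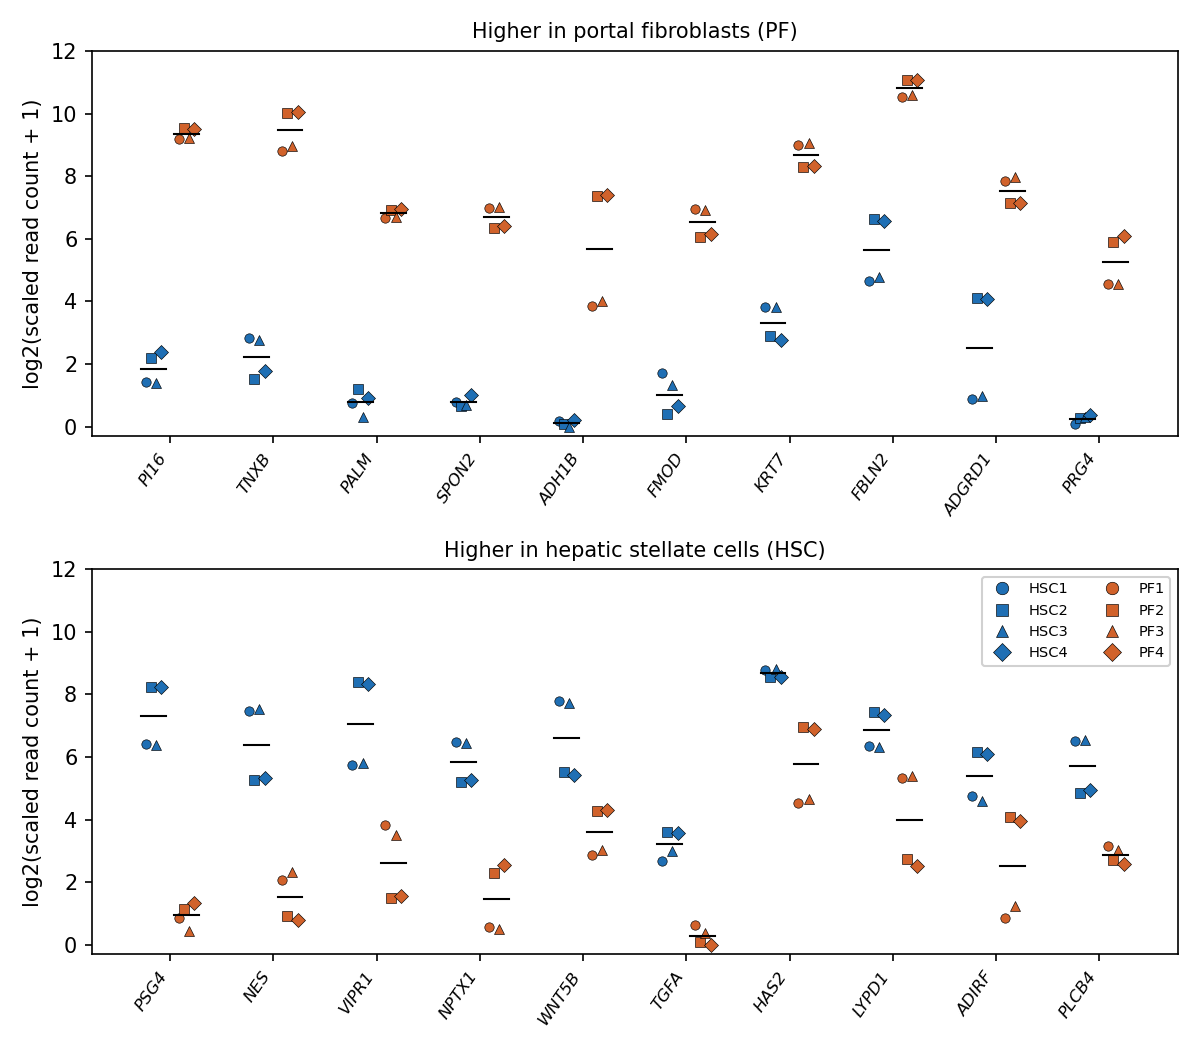
Per-library levels, as log2 of the scaled read count + 1, of the 10 genes with the largest difference in each direction, with HSC libraries in blue, PF libraries in orange and black lines at the mean of 4 libraries. All 4 libraries of the higher cell type lie above all 4 of the other for each gene, and the levels of HSC and PF libraries often fall into pairs, as for ADH1B in PF.

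The 10 genes with the largest difference toward PF were PI16, TNXB, PALM, SPON2, ADH1B, FMOD, KRT7, FBLN2, ADGRD1 and PRG4, and all 10 held in both tests. PI16 (GRCh38 chromosome 6, 36948263 to 36964837) was higher by 7.51 ± 0.24 (SE) on the log2 scale, with an adjusted p of 3.34e-06 in limma. TNXB, which encodes the matrix glycoprotein tenascin-X, stood at 763 ± 336 in PF and 4.08 ± 2.22 in HSC, although its reads can be shared with the near-identical pseudogene TNXA. PALM, a membrane-bound phosphoprotein gene, was measured at 111 ± 11.3 against 0.768 ± 0.442. SPON2, a secreted matrix protein gene, was at 104 ± 25.3 against 0.729 ± 0.195. The alcohol dehydrogenase gene ADH1B was nearly absent from HSC (0.0825 ± 0.0641), and in PF it ranged from 13.5 and 15.2 in PF1 and PF3 to 164 and 169 in PF2 and PF4. The proteoglycan genes FMOD and PRG4 were at 94.6 ± 30.5 and 42.7 ± 23.6 in PF, against 1.16 ± 0.879 and 0.196 ± 0.0976 in HSC. ADGRD1, an adhesion G protein-coupled receptor gene, was at 190.0 ± 57.0 against 8.46 ± 8.73. KRT7 (chromosome 12, 52232520 to 52252186), a keratin of bile duct and other simple epithelia, was higher by 5.35 ± 0.31 (SE).

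Toward HSC the 10 largest differences were those of PSG4, NES, VIPR1, NPTX1, WNT5B, TGFA, HAS2, LYPD1, ADIRF and PLCB4, of which all except ADIRF held in both tests. PSG4 (chromosome 19, 43192702 to 43207299) belongs to the pregnancy-specific glycoprotein family, whose near-identical members can share reads, and its log2 difference of -6.38 ± 0.49 (SE) is uncertain for that reason. NES (chromosome 1, 156668763 to 156677397) differed by -4.87 ± 0.65 (SE), with an adjusted p of 0.00174 in limma. The neuronal pentraxin gene NPTX1 was at 62.2 ± 29.3 in HSC and 2.41 ± 2.29 in PF. WNT5B, a noncanonical WNT ligand gene, was at 129 ± 99.3 against 12.6 ± 6.80, and the growth factor gene TGFA at 8.66 ± 2.90 against 0.231 ± 0.255. HAS2, which encodes a hyaluronan synthase, was at 409.8 ± 39.7 in HSC and 72.0 ± 56.2 in PF. PLCB4, a phospholipase C gene, was at 60.1 ± 36.2 against 6.39 ± 1.38, and LYPD1 at 124 ± 50.5 against 22.7 ± 20.1. For ADIRF the levels were 46.8 ± 25.8 in HSC and 8.17 ± 8.22 in PF, with an adjusted p of 0.0363 with libraries as separate and 0.0618 with pairs as correlated.

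Of 34 gene lists fixed before the data were examined, 32 had at least 5 tested genes, and 15 of them passed camera with a preset correlation of 0.01 (limma package, adjusted p below 0.05). These set tests have the same limit as the gene tests, and with an estimated correlation between genes only 1 list, that of elastic fibre genes, passed, and with pair means and an estimated correlation 0. Other splits of the 8 libraries into 4 and 4 put up to 17 lists past the test, and the 2 that keep pairs whole put 4 and 7. The description that follows therefore gives member counts and values. Unless stated otherwise, the counts come from limma on 8 libraries and share its limit. Among all 13145 tested genes 1813 were higher and 1615 lower in PF, and counts near that share do not set a list apart. With pairs as correlated the counts were smaller in most lists.

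**Figure D2:**
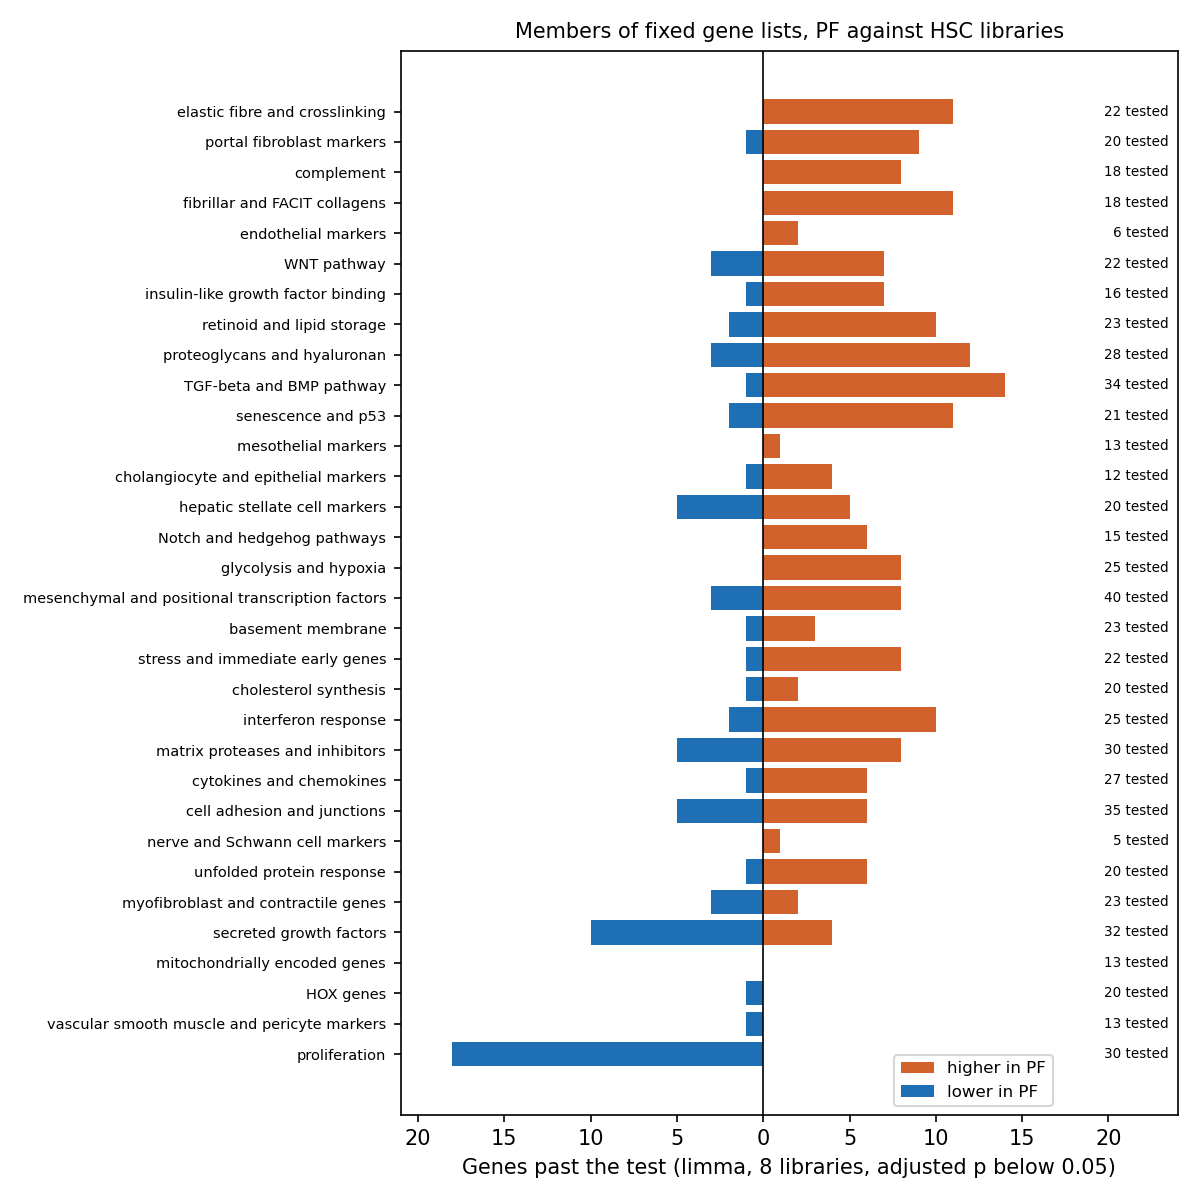
Number of members of each fixed gene list with at least 5 tested genes that passed the limma test on 8 libraries, with genes higher in PF to the right in orange, genes lower in PF to the left in blue and the number tested at the right edge. Elastic fibre genes had 11 members higher and none lower in PF, and proliferation genes had 18 lower and none higher. With pairs as correlated, 9 elastic fibre genes were higher and 4 proliferation genes lower.

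Portal fibroblast markers were higher in PF for 9 of 20 tested members and lower for 1, and for 9 and 1 adjusted over the list alone. The camera test gave an adjusted p of 8.39e-04, and adjusted p = 0.137 with an estimated correlation. After PI16 and FBLN2, the member with the largest difference was FBLN1, another fibulin gene, at 272 ± 29 in PF against 2.0 and 1.56 in HSC1 and HSC3 and 48.1 and 51.3 in HSC2 and HSC4. COL15A1, a collagen gene of portal and adventitial fibroblasts, was higher but low, at 4.36 ± 2.57 against 0.866 ± 0.315, and passed with libraries as separate (adjusted p = 0.0228) but not with pairs as correlated (0.207). SLIT2, an axon guidance ligand gene, was lower in PF, at 16.9 ± 6.79 against 88.5 ± 5.76, and held in both tests. The surface marker THY1 was abundant in both cell types, at 1043 ± 164 in PF and 753 ± 397 in HSC (adjusted p = 0.243). The elastin gene ELN differed among PF libraries more than between cell types, at 5.32 and 5.08 in PF1 and PF3 and 548 and 565 in PF2 and PF4, against 21.9 ± 22.1 in HSC (adjusted p = 0.395). MSLN, a mesothelial and portal fibroblast marker, averaged 0.669 ± 0.548 in PF and 0.0821 ± 0.0638 in HSC (adjusted p = 0.139), and GLI1 lay under the filter on low values.

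Hepatic stellate cell markers were divided, with 5 of 20 members higher and 5 lower in PF, and 7 and 6 adjusted over the list alone. The list's median log2 difference was 0.49, its mean -0.13 and its camera adjusted p 0.739, so the mean and the median differed in sign, and the set test pointed with the median toward PF. NES and VIPR1 were lower in PF in both tests. HGF, the hepatocyte growth factor gene, was at 14.3 ± 2.18 in HSC and 5.42 ± 4.15 in PF, and passed with libraries as separate (adjusted p = 0.0438) but not with pairs as correlated (0.168). The stellate cell globin gene CYGB ran the other way, at 66.0 ± 48.9 in PF and 1.53 ± 0.469 in HSC, as did BAMBI, a TGF-beta pseudoreceptor gene, at 106 ± 55.9 against 21.2 ± 4.67. Both held in both tests. COLEC10, a collectin gene, was at 15.6 ± 8.10 in PF and 3.76 ± 2.46 in HSC, with adjusted p = 0.0279 with libraries as separate and 0.124 with pairs as correlated. The pericyte gene RGS5 was at 405 and 406 in HSC1 and HSC3 but at 1.95 and 1.51 in HSC2 and HSC4, with PF libraries at 10.7 ± 4.0 (adjusted p = 0.544). Its log2 difference of -1.58 became 2.03 without HSC1 and HSC3 and -5.19 without HSC2 and HSC4, each time with only 1 pair left in HSC. RELN averaged 11.7 ± 11.1 in HSC and 37.6 ± 42.5 in PF, and DES 3.97 ± 4.32 and 6.64 ± 1.13, with adjusted p-values of 0.822 and 0.239. PDGFRB and PDGFRA, receptors for platelet-derived growth factors, did not pass in limma either, at 106 ± 39.3 and 223 ± 119 in HSC and 171 ± 37.8 and 367 ± 103 in PF (adjusted p = 0.0853 and 0.154). LRAT was not analysed here.

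Elastic fibre and crosslinking genes had 11 of 22 members higher in PF and 0 lower (14 and 0 adjusted over the list alone), with a camera adjusted p of 6.58e-08 and adjusted p = 0.0292 with an estimated correlation. With pair means and an estimated correlation the call was lost (adjusted p = 0.385). Several members, among them FBLN1 and FBLN2, are also in the list of portal fibroblast markers, so the results of these lists are not separate. Besides the fibulins, the microfibril gene FBN2 was at 55.2 ± 34.9 in PF against 1.56 ± 1.44 in HSC and held in both tests. Fibrillar and FACIT collagens had 11 of 18 members higher and 0 lower (12 and 1 adjusted over the list alone), with camera adjusted p = 0.00269 and adjusted p = 0.166 with an estimated correlation. With pairs as correlated, 6 were higher and 0 lower. COL1A1 was at 17948 ± 2073 in PF and 7268 ± 1908 in HSC, COL3A1 at 7888 ± 2880.2 and 3129.8 ± 293, and COL16A1 at 404 ± 64.7 and 107 ± 65.2. These 3 held in both tests. Proteoglycan and hyaluronan genes had 12 of 28 higher and 3 lower (12 and 3 adjusted over the list alone), with camera adjusted p = 0.00269 and adjusted p = 0.145 with an estimated correlation. Decorin (DCN) was at 2241 ± 1142 against 643 ± 249 and lumican (LUM) at 431 ± 183 against 171 ± 34.9, and both held in both tests, whereas biglycan (BGN) was at 686 ± 70.4 against 527 ± 212 (adjusted p = 0.240). Among the lower members, CD44, the hyaluronan receptor gene, was at 631 ± 114 in PF and 1258 ± 64.7 in HSC. Of 23 basement membrane genes, with camera adjusted p = 0.282, 0 were called with pairs as correlated. With libraries as separate 3 were higher and 1 lower, the same numbers adjusted over the list alone. Of these, the collagen IV chain gene COL4A4 was at 24.7 ± 24.6 in PF and 0.854 ± 0.443 in HSC and the laminin gene LAMB3 at 4.75 ± 0.697 and 13.2 ± 2.88, and neither passed with pairs as correlated (adjusted p = 0.0714 and 0.0656). Matrix proteases and their inhibitors went both ways, with 8 of 30 higher and 5 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.285). The protease inhibitor gene SERPINE2 was at 4102 ± 409.7 in PF, 80.4 and 79.6 in HSC1 and HSC3, and 664 and 649 in HSC2 and HSC4. The collagen-degrading protease gene CTSK was higher in PF at 153 ± 68.4 against 29.1 ± 20.1 and the urokinase receptor gene PLAUR lower at 59.1 ± 4.95 against 120.1 ± 15.9, and these 3 genes held in both tests.

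Secreted growth factor genes were lower in PF for 10 of 32 members and higher for 4 (11 and 5 adjusted over the list alone), although the list did not pass camera (adjusted p = 0.178). The epidermal growth factor family member HBEGF was at 36.5 ± 0.672 in HSC and 4.69 ± 1.75 in PF, KITLG at 60.1 ± 11 and 19.7 ± 9.73, and FGF9, which was higher in PF, at 1.34 ± 1.55 and 11.6 ± 5.11. These 3 held in both tests. In the TGF-beta and BMP list 14 of 34 members were higher and 1 lower in PF (15 and 1 adjusted over the list alone), with camera adjusted p = 0.00165 and adjusted p = 0.0895 with an estimated correlation. BMP6 was at 37.4 ± 11 in PF and 0.955 ± 0.739 in HSC, GDF15 at 61.0 ± 32.4 and 10.1 ± 4.72, and the activin subunit gene INHBA, the lower member, at 209 ± 110.5 and 588 ± 153. These 3 held in both tests. WNT genes had 7 of 22 higher and 3 lower (8 and 3 adjusted over the list alone), with camera adjusted p = 0.0456 and adjusted p = 0.235 with an estimated correlation. The WNT amplifier RSPO3 was at 22.4 ± 2.19 in PF and 1.29 ± 1.37 in HSC, and the noncanonical ligand WNT5A, like WNT5B, was lower in PF at 28.5 ± 4.22 against 84.0 ± 22.2. WNT2 was at 3.63 and 4.85 in PF1 and PF3, at 34.6 and 34.7 in PF2 and PF4 and at 0.624 ± 0.306 in HSC, and did not pass with pairs as correlated (adjusted p = 0.0561). Notch and hedgehog genes had 6 of 15 higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 0.0145 and adjusted p = 0.137 with an estimated correlation. GAS1, a hedgehog co-receptor gene, was at 79.4 ± 23.8 against 1.80 ± 0.567, and SMO, the hedgehog signal transducer gene, at 21.7 ± 3.09 against 2.60 ± 1.45. Insulin-like growth factor binding genes had 7 of 16 higher and 1 lower, the same numbers adjusted over the list alone, with camera adjusted p = 0.00521 and adjusted p = 0.114 with an estimated correlation. IGFBP3 was at 1725 ± 242 in PF and 214 ± 23.3 in HSC.

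Complement genes were higher in PF for 8 of 18 members and lower for 0 (9 and 0 adjusted over the list alone), with camera adjusted p = 0.00220 and adjusted p = 0.235 with an estimated correlation. CFB, complement factor B, was at 284 ± 231 in PF against 9.20 ± 1.18 in HSC, and C1R, the C1 protease gene, at 566 ± 193 against 72.5 ± 51.1. Both held in both tests. Of 27 cytokine and chemokine genes 6 were higher and 1 lower, the same numbers adjusted over the list alone, and the list did not pass (camera adjusted p = 0.313). IL6 was at 323 ± 171 in PF and 37.9 ± 25.2 in HSC and CSF1 at 109 ± 9.0 and 47.9 ± 18.2. Each passed in both tests. Interferon response genes had 10 of 25 higher and 2 lower (11 and 2 adjusted over the list alone), with camera adjusted p = 0.0749. With pairs as correlated, 2 members of this list were higher and 0 lower. The helicase gene DDX58, which went against the direction of most called members, was lower in PF at 10.5 ± 3.07 against 26.2 ± 2.12, but not with pairs as correlated (adjusted p = 0.111).

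Proliferation genes were lower in PF for 18 of 30 members and higher for 0 (25 and 0 adjusted over the list alone). With pairs as correlated, only 4 were lower and 0 higher. Camera gave an adjusted p of 3.74e-08, and adjusted p = 0.371 with an estimated correlation, which was 0.798 in this list. The mitotic checkpoint kinase gene BUB1 was at 33.7 ± 11.2 in HSC and 9.51 ± 5.38 in PF, and RRM2, a ribonucleotide reductase subunit gene, at 58.7 ± 9.64 and 19.9 ± 10.0. Both held in both tests. The list's median level was 8.82 and 9.58 in PF1 and PF3, 27.1 and 26.3 in PF2 and PF4, 29.4 and 30.3 in HSC2 and HSC4, and 53 and 52.1 in HSC1 and HSC3. Senescence and p53 genes had 11 of 21 higher and 2 lower, the same numbers adjusted over the list alone, with camera adjusted p = 0.00573 and adjusted p = 0.114 with an estimated correlation. The lower members were CCND1, a cell cycle entry gene, at 544 ± 73.2 in PF and 2408 ± 486 in HSC, and the chromatin protein gene HMGA2, at 18.5 ± 9.18 and 72.0 ± 12.8. Each passed in both tests. CDKN1C, a cyclin-dependent kinase inhibitor gene, was low in PF at 3.19 ± 0.372 and lower in HSC at 0.0848 ± 0.10. Glycolysis and hypoxia genes had 8 of 25 higher and 0 lower (9 and 0 adjusted over the list alone), with camera adjusted p = 9.03e-04 and adjusted p = 0.444 with an estimated correlation. NDRG1, a hypoxia-responsive gene, was at 280.5 ± 59.1 against 56.0 ± 12.1, and ADM, the adrenomedullin gene, at 119 ± 28.3 against 42.7 ± 2.18. Unfolded protein response genes had 6 of 20 higher and 1 lower (camera adjusted p = 0.282), cholesterol synthesis genes 2 of 20 higher and 1 lower (0.282), and stress and immediate early genes 8 of 22 higher and 1 lower (0.0624), each with the same numbers adjusted over the list alone. Of these lists, the stress-induced gene CHAC1 was at 47.5 ± 7.13 in PF and 11.3 ± 3.05 in HSC, the cholesterol transporter gene STARD4, the lower member, at 31.0 ± 6.64 and 78.6 ± 24.9, and the immediate early genes KLF4 and KLF6 at 73.8 ± 28.5 and 95.4 ± 3.54 in PF and 9.07 ± 0.197 and 219.6 ± 48.1 in HSC. These 4 held in both tests.

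Mesenchymal and positional transcription factors had 8 of 40 members higher and 3 lower in PF, the same numbers adjusted over the list alone, with camera adjusted p = 0.0454 and adjusted p = 0.371 with an estimated correlation. With pairs as correlated, 2 were higher and 1 lower. GATA6 was at 104 ± 5.28 in PF, at 4.72 and 6.34 in HSC1 and HSC3 and at 34.3 and 32.9 in HSC2 and HSC4, and TBX3, the member with the largest difference toward HSC, at 9.73 ± 2.87 against 65.9 ± 32.3; both held in both tests. Among 20 HOX genes, which keep positional identity, 1 was lower and 0 higher (0 and 0 adjusted over the list alone), with camera adjusted p = 0.567. The lower one was HOXB2, at 21.5 ± 5.79 in PF and 32.1 ± 2.75 in HSC (adjusted p = 0.0477, and 0.236 with pairs as correlated). Retinoid and lipid storage genes had 10 of 23 higher and 2 lower in PF, the same numbers adjusted over the list alone, with camera adjusted p = 0.00573 and adjusted p = 0.240 with an estimated correlation. RDH10, a retinol dehydrogenase gene, was at 356 ± 93.2 in PF and 46.6 ± 25.8 in HSC, and CRABP2, a retinoic acid binding protein gene, at 26.2 ± 7.36 and 3.79 ± 0.991. Both held in both tests. PPARG, a regulator of lipid storage and of stellate cell quiescence, was lower in PF at 3.48 ± 0.997 against 9.38 ± 0.884 with libraries as separate (adjusted p = 0.00227) but not with pairs as correlated (0.146).

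Contractile and myofibroblast genes gave no common direction, with 2 of 23 higher and 3 lower, the same numbers adjusted over the list alone. Their median log2 difference was -0.057, their mean 0.12 and their camera adjusted p 0.756, with mean and median again of opposite sign and the set test pointing with the median toward HSC. ACTA2, the smooth muscle actin gene used as a myofibroblast marker, was at 3972 and 3991 in PF1 and PF3, 212 and 209 in PF2 and PF4, 1568 and 1583 in HSC1 and HSC3, and 69.4 and 65.7 in HSC2 and HSC4 (adjusted p = 0.501). SMTN, which encodes the actin-binding protein smoothelin, was lower in PF at 66.9 ± 4.33 against 189 ± 19.3 and held in both tests. Vimentin (VIM), the general mesenchymal intermediate filament, was at 4271 ± 788 in PF and 6016 ± 217 in HSC (adjusted p = 0.0535). Adhesion and junction genes had 6 of 35 higher and 5 lower (6 and 6 adjusted over the list alone), with camera adjusted p = 0.739. The collagen-binding integrin subunit gene ITGA11 was at 310.2 ± 132 in PF and 56.9 ± 17.0 in HSC, and ITGA2 at 70.5 ± 23.6 and 279 ± 82.0, in opposite directions that held in both tests.

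**Figure D3:**
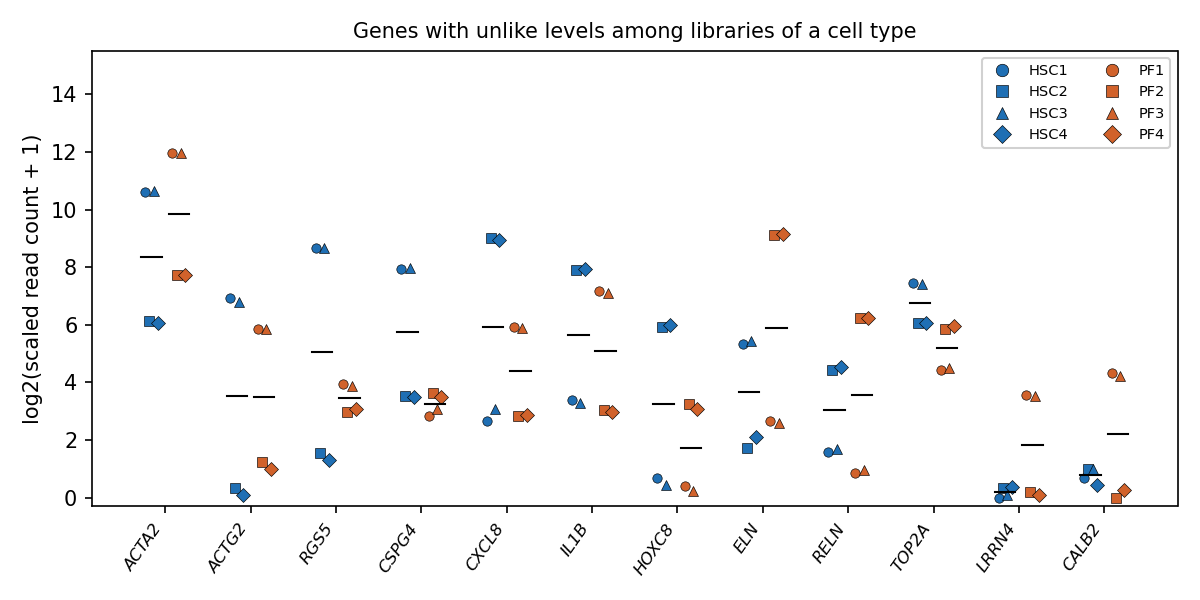
Per-library levels, as log2 of the scaled read count + 1, of 12 genes that differed among libraries of a cell type, chosen after their values were seen, with HSC libraries in blue, PF libraries in orange and black lines at the mean of 4 libraries. HSC1 lies with HSC3, HSC2 with HSC4, PF1 with PF3 and PF2 with PF4, and ACTA2 spans 65.7 to 1583 scaled counts in HSC and 209 to 3991 in PF.

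Of 25 hepatocyte markers 3 were tested, with 0 higher and 0 lower in PF, and of 23 leukocyte and Kupffer cell markers 4 were tested, with 1 higher and 1 lower, too few for a set test. CD14, the higher member of the latter, was at 10.0 ± 5.52 in PF and 1.20 ± 0.534 in HSC. Of 6 tested endothelial markers 2 were higher and 0 lower (2 and 1 adjusted over the list alone), with camera adjusted p = 0.145, and CDH5, the endothelial cadherin gene, was at 6.65 ± 0.410 against 0.851 ± 0.386 without passing with pairs as correlated (adjusted p = 0.0959). Cholangiocyte and epithelial markers had 4 of 12 higher and 1 lower (5 and 2 adjusted over the list alone), with camera adjusted p = 0.0456 and adjusted p = 0.235 with an estimated correlation. Next to KRT7, the mucin gene MUC1 was at 19.8 ± 3.27 in PF against 4.67 ± 1.09 in HSC, while SOX9, a transcription factor of bile duct cells, was lower in PF at 0.976 ± 0.645 against 6.84 ± 1.71, with adjusted p = 0.00152 with libraries as separate and 0.0853 with pairs as correlated. Mesothelial markers had 1 of 13 higher and 0 lower (camera adjusted p = 0.0930), nerve and Schwann cell markers 1 of 5 higher and 0 lower (0.773), and smooth muscle and pericyte markers 0 of 13 higher and 1 lower (0.552), each with the same numbers adjusted over the list alone. The median level of the smooth muscle and pericyte list was 135 and 144 in HSC1 and HSC3, 10.6 and 10.3 in HSC2 and HSC4 and 10.4 to 13.0 in PF. That of the mesothelial list was 19.1 and 17.8 in PF1 and PF3, 2.30 and 2.50 in PF2 and PF4 and 2.39 to 3.74 in HSC. The lower member of the smooth muscle and pericyte list was RGS4, a regulator of G protein signalling, at 342 ± 62.2 in PF and 1157 ± 519 in HSC, which held in both tests. No mitochondrially encoded gene passed (0 of 13, the same number adjusted over the list alone, camera adjusted p = 0.282). Their share of reads was 2.39% and 2.34% in PF1 and PF3, 4.36% and 4.42% in PF2 and PF4, and 3.43% to 4.67% in HSC.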

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

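The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries and the comparison of same-numbered columns. Over 290 groups of 4 libraries, 2 had 1 library further from the others than Dixon's 95% limit allows, where chance alone gives about 1 in 20 groups of 4 independent libraries. Because the 4 libraries of a type fall into 2 close pairs, 1 library rarely stands apart, so the count cannot be set against that rate. For SMTN in PF the gap was 0.855 of the range, with PF2 at 60.5 and the others at 68.5 to 69.9. For the median of the cholesterol synthesis list in PF it was 0.927, with PF1 at 80.4 and the others at 73.9 to 74.4.

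Whether the number of called genes depends on the grouping by cell type was tested over the 35 splits of the 8 libraries into 4 and 4. Only 1 split, the real one, called as many as 3428 genes, and the highest other split called 533. The 2 other splits that kept all pairs whole called 275 and 533 genes. Splits that part a pair put nearly equal libraries on both sides. Only the 3 splits that part no pair are comparable, which is too few for a share under 0.05. For gene lists, 5 of the 35 splits put at least 15 lists past the test, with 17 in the highest other split, which parted pairs. The other splits with pairs whole put 4 and 7 past it, again too few splits for a share under 0.05.

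KRT7, a keratin of bile duct epithelium, was higher in PF, and cholangiocytes or mesothelial cells among the cultured cells could bring it. Cholangiocytes would bring the other members of the epithelial list, but the median PF level of these 11 genes was 3.17 scaled counts against 420.0 for KRT7, and 8 of them stood under 0.1 times the level of KRT7. Outside the keratins the highest was MUC1 at 19.8, so the members above that cut were other keratins. For mesothelial cells, the median over the 10 members other than keratins was at most 8.90 in any PF library. The mesothelial genes LRRN4 and CALB2 were at 10.7 and 19.1 in PF1 but 0.135 and 0 in PF2, while KRT7 was 515 in PF1 and 311 in PF2. KRT7 thus differed in the same direction as the mesothelial markers other than keratins, whose median was 8.90 in PF1 and 1.42 in PF2, but by a smaller factor. No levels of pure cholangiocytes or mesothelial cells were at hand, so the cut at 0.1 cannot exclude either cell type as a source. A hypothesis that also stays open is that PF express KRT7 themselves in culture.

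The proliferation list was lower in PF, although camera with an estimated correlation did not call it (adjusted p = 0.371). The growth state of single cultures may account for part of the difference. The list's median log2 difference was -1.36 over all libraries, and between single PF and HSC libraries it ranged from -2.67 to -0.22, below 0 in all 16 comparisons. These comparisons are not independent, because partners in a pair are nearly equal. With the smallest difference far nearer to 0 than the median, growth state stays open beside cell type, and the design holds no measure of growth. With scaling by total reads in place of the deposited factors the list's median difference was -1.46. The median gene moved by only -0.11 between these scalings, so this outcome was largely fixed in advance. It shows only that the choice between them cannot produce a difference of this size.

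ACTA2 was at 1568 in HSC1 and 69.4 in HSC2, while the median of the myofibroblast and contractile list was 369 to 383 over the HSC libraries. Pericytes or smooth muscle cells among the cells of HSC1 and HSC3 could bring ACTA2: of 12 members of the smooth muscle and pericyte list with a mean of at least 5, 10 were higher there and 2 (KCNJ8 and ABCC9) lower. Because stellate cells themselves express many of these genes, such cells and a state of the stellate cells cannot be told apart, although MYH11, a marker of mature smooth muscle, was at 0.908 and 0.718. A donor, batch or growth state shared by same-numbered columns of both cell types could give deviations that go together over all genes. The lowest Pearson r over genes (not independent) was -0.0408, and no pairing of columns exceeded 0.05 in size. Because partners are nearly equal and deviations were taken from the cell type mean, these correlations repeat each other apart from the sign. They show only that the difference between HSC pairs was nearly unrelated over all genes to that between PF pairs. No label ties column numbers to a donor or batch, so this comparison cannot exclude a shared donor or batch. A shared state limited to few genes also stays open, with ACTA2 at 3972 in PF1 and 212 in PF2.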

How the results depend on the processing

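No paired analysis was possible because the columns carry no donor, and the planned donor means, donor blocks, donor contrasts and cell type by donor term were not run for the same reason. Pair-based fits, edgeR, DESeq2, scaling by total reads and leaving out a pair were chosen after seeing the data. Pair means, pairs as correlated and other eBayes settings keep the log2 differences of limma on 8 libraries, so no direction could change there. For 3397 of the 3428 genes called, every library of 1 cell type lay above every library of the other. Leaving out libraries or changing the pseudocount could not turn these genes. Within these limits, none of the 3428 genes called with limma on 8 libraries changed direction in any alternative in which it was tested. The count was 628 with pairs as correlated, 0 with limma on pair means, 0 with edgeR and 684 with DESeq2 on reads summed over pairs, and 1157 with an absolute log2 difference of at least 1. At an unadjusted p below 0.05, pair means gave 1607 genes and summed reads in edgeR 1595. These fits use fewer samples or count partners as correlated, and the last keeps only larger differences. Other alternatives for the 8 libraries gave 3187 to 4385 genes, leaving out 1 library 2501 to 2994 and leaving out 1 pair 3552 to 4905. Among 105 tested genes in the text, 84 were called, of which 13 were not with pairs as correlated and 84 not with pair means. Genes with few reads are limited by depth, and 102 of the 105 kept a value of at least 5 in 2 libraries.

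Of 15 lists called with the preset correlation, none changed direction. The count was 1 with an estimated correlation and 0 with pair means and an estimated correlation, leaving out 1 library gave 12 to 16 lists and leaving out 1 pair 13 to 18. With an estimated correlation the adjusted p was 0.137 for portal fibroblast markers and Notch and hedgehog pathways, 0.166 for fibrillar and FACIT collagens, 0.145 for proteoglycans and hyaluronan and 0.240 for retinoid and lipid storage. It was 0.0895 for TGF-beta and BMP pathway, 0.235 for WNT pathway, complement and cholangiocyte and epithelial markers, 0.371 for mesenchymal and positional transcription factors and proliferation and 0.114 for senescence and p53 and insulin-like growth factor binding. The value was 0.444 for glycolysis and hypoxia. With pair means and an estimated correlation it was 0.465 for mesenchymal and positional transcription factors and proliferation and 0.581 for glycolysis and hypoxia, and 0.385 for the other 12 called lists. With pair means and the preset correlation the adjusted p was 0.0288 for stress and immediate early genes, against 0.385 with pair means and an estimated correlation. With quantile normalization the adjusted p was 0.0674 for cholangiocyte and epithelial markers. With total reads the adjusted p was 0.0331 for interferon response, 0.0264 for mesothelial markers and 0.0429 for stress and immediate early genes. With the deposited factors and an estimated correlation these lists had 0.220, 0.258 and 0.258. With no filter the adjusted p was 0.0523 for WNT pathway. With a minimum of 5 the adjusted p was 0.958 for hepatic stellate cell markers, 0.136 for WNT pathway and cholangiocyte and epithelial markers and 0.0980 for mesenchymal and positional transcription factors. In the last of these the stellate cell markers pointed toward HSC in place of PF. The causes were not tested.

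Leaving out a library or a pair changed the call or the direction of some lists. Their adjusted p ranged from 0.236 to 0.943 for hepatic stellate cell markers, 0.0177 to 0.920 for myofibroblast and contractile genes, 0.0185 to 0.969 for basement membrane and 0.00129 to 0.127 for proteoglycans and hyaluronan. It ranged from 0.0363 to 0.539 for secreted growth factors, 0.00416 to 0.248 for WNT pathway, 0.0110 to 0.0587 for Notch and hedgehog pathways and 0.0292 to 0.943 for cytokines and chemokines. The range was 0.0145 to 0.311 for interferon response, 0.0121 to 0.943 for HOX genes, 0.00291 to 0.436 for mesenchymal and positional transcription factors and 0.0159 to 0.943 for cholesterol synthesis. For more lists it was 1.87e-05 to 0.127 for glycolysis and hypoxia, 0.0159 to 0.670 for unfolded protein response, 0.00434 to 0.305 for cholangiocyte and epithelial markers and 0.0113 to 0.378 for mesothelial markers. It ranged from 0.0146 to 0.858 for vascular smooth muscle and pericyte markers, 0.0131 to 0.663 for stress and immediate early genes and 0.0113 to 0.788 for mitochondrially encoded genes. Of these, the direction turned for HOX genes, cholesterol synthesis, cytokines and chemokines, hepatic stellate cell markers, mitochondrially encoded genes, myofibroblast and contractile genes, unfolded protein response and vascular smooth muscle and pericyte markers, none of which was called with 8 libraries. The causes were not tested.

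The genes whose direction turned were all uncalled with 8 libraries. Leaving out a library or a pair gave log2 differences of -1.06 to 0.73 for ABCC9, -0.78 to 3.74 for ACTA2, -3.38 to 3.26 for ACTG2, -0.058 to 0.99 for BGN and -0.65 to 3.50 for CALB2. It gave -4.60 to 1.52 for CXCL8, -0.20 to 2.62 for DES, -1.03 to 5.46 for ELN, -4.23 to 1.18 for HOXC8 and -2.85 to 1.74 for IL1B. The range was -0.058 to 3.34 for LRRN4, -2.15 to 3.18 for RELN, -5.19 to 2.03 for RGS5 and -0.084 to 1.33 for THY1. With a pseudocount of 0.1 the difference for ACTG2 was 0.66, and with 1 it was -0.057. These genes had unlike levels in the pairs of a cell type, so which pair stays decides the sign.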

Other observations

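Libraries of a cell type differed in single genes that the comparison of cell types averages over. The examples come from the fixed lists, were chosen after their values were seen and are given as values without tests. CXCL8, a neutrophil chemokine, was at 513 and 495 in HSC2 and HSC4, 5.27 and 7.42 in HSC1 and HSC3, 59.6 and 58.0 in PF1 and PF3 and 6.22 and 6.33 in PF2 and PF4. IL1B, the inflammatory cytokine gene, was at 241 and 244 in HSC2 and HSC4, 9.39 and 8.80 in HSC1 and HSC3, 142 and 138 in PF1 and PF3 and 7.31 and 6.79 in PF2 and PF4. CSPG4, a pericyte gene, was at 245 and 249.6 in HSC1 and HSC3, against 10.6 and 10.3 in HSC2 and HSC4 and 6.12 to 11.4 in PF. ACTG2, a smooth muscle actin gene, was at 120.1 and 111 in HSC1 and HSC3 and 56.2 and 57.2 in PF1 and PF3, and at most 1.35 in the other 4 libraries. The HOX gene HOXC8 was at 60.3 and 63.3 in HSC2 and HSC4, 8.52 and 7.38 in PF2 and PF4 and at most 0.606 in the other 4. RELN, an extracellular glycoprotein gene of stellate cells, was at 2.0 and 2.21 in HSC1 and HSC3, 20.4 and 22.1 in HSC2 and HSC4, 0.806 and 0.934 in PF1 and PF3 and 73.5 and 75.3 in PF2 and PF4. TOP2A, a gene of dividing cells, was at 176 and 169 in HSC1 and HSC3, 66.1 and 66.4 in HSC2 and HSC4, 20.7 and 21.4 in PF1 and PF3 and 57.2 and 61.4 in PF2 and PF4.

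Outside the fixed lists, MT2A and MT1E, metallothionein genes that bind zinc and copper, were lower in PF, and were chosen after their values were seen. MT2A was at 457 ± 104 in PF and 978 ± 19.8 in HSC, with adjusted p = 0.00219 with libraries as separate and 0.00636 with pairs as correlated. MT1E was at 38.9 ± 17.3 against 123 ± 59.1, with adjusted p = 0.0259 and 0.0410, although members of this family share near-identical sequence.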
